A study of Homo sapiens with 4 samples.

How the data were processed

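RNA from K562 cells with an SF3B1 wild-type knock-in (2 libraries) or the SF3B1 K700E change (2 libraries) was sequenced as polyadenylated RNA; the labels state 60 M paired-end reads for each library. Per the submitters' processing notes the reads were aligned with STAR to hg19. The STAR version, the gene annotation behind its annotated flag, the alignment settings and the library kit are not given in the sources used here. The authors deposited 1 junction table per library, with 9 columns and no header, which has the layout of STAR's junction output. The deposited counts are raw, whole numbers of uniquely mapped and of multi-mapping reads crossing each junction, with no normalization; other columns give codes for strand, intron motif and annotation, and the longest overhang in nt. Junction tables hold only spliced reads, so retained introns, single-exon genes and the base behind SF3B1 K700E cannot be read from them, and the genotype rests on the labels. Libraries were grouped by the genotype label.

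The 4 tables were merged on position, strand and motif. Tests used junctions with an assigned strand and motif; junctions of undefined strand held 0.042% to 0.049% of the unique reads. For acceptor choice, each junction's unique reads were set against the other reads of the same donor in pairs of columns per library, and for donor choice against the other reads of the same acceptor. For exon skipping, the reads of the skipping junction were set against the sum over the pair of inclusion junctions, for exons of up to 1000 nt, and the skipping level is the skipping reads over those reads plus the mean of the inclusion junctions. The model had the library as a factor, the column kind, and the interaction of kind with genotype as the tested term. Tested junctions had at least 10 unique reads over the 4 libraries and at least 20 reads in the group in every library. For acceptors and donors, but not for skipping, the dominant junction of the group was left out. It is the one with the highest mean usage over the 4 libraries. A call needed a Benjamini-Hochberg adjusted p below 0.05 and a difference of mean usage of at least 10 percentage points. Positions relative to the dominant site run along the transcript, negative being upstream.

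The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust estimation. The dispersion setting was changed after a first run on the real counts. That run used an estimated negative-binomial dispersion and called 253 acceptors higher and 90 lower, 43 and 30 donors, and 50 and 157 skipping events. On simulated counts it recovered few of the changes in donors and skipping and part of those in acceptors, so 12 settings were compared for each of the comparisons on simulated counts, and a dispersion of 0, under which the quasi-dispersion carries the spread between libraries, was taken because no other setting recovered more changes of 30 points and false calls were few. The choice was made with the first counts known and it raised them, to 306 and 173, 124 and 115, and 165 and 441. The simulated counts were beta-binomial with 1 correlation per comparison, a form close to what the chosen model assumes, which favours it. Every simulated change of usage or skipping level was a rise in K700E. The recovery of falls was therefore not measured, for acceptors, donors or skipping. In the self-test on the 21005 tested acceptors, with 200 changed, this setting recovered 67% of changes of 15 points and 98% of changes of 30 points with 0 false calls. For the 19321 donors it recovered 64% and 94% with 4 false calls, and for the 47947 skipping events 31% and 76% with 2 false calls. The first setting recovered 34% and 73%, 4% and 33%, and 0% and 3%. In the simulation used to compare settings, with a slightly different correlation, the first setting recovered 53%, 50% and 26% of the changes of 30 points and the chosen one 96%, 92% and 79%.

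For spliced reads by locus, unique reads were summed over annotated introns joined by a shared donor or acceptor, because no annotation of hg19 was used. These sums were tested with filterByExpr, TMM normalization and edgeR's quasi-likelihood test on genotype. Standard errors of log2 fold changes come from the F statistic, and CPM are counts scaled to the TMM library size. In its self-test on 92154 intron groups, 14% of 2-fold and 82% of 4-fold changes were recovered with 3 false calls. Shares of counts have Wilson or exact binomial 95% intervals, and the position of gained acceptors was tested with Fisher's exact test. At the depth of these libraries, 3 reads are between 9.82e-06% and 2.12e-05% of a library's unique junction reads.

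The tests, the filters, the alternatives and the rule for naming junctions were fixed before the data were examined, except as stated here and below. The rule named the 20 acceptors with the largest absolute change among those called, with both K700E libraries beyond both wild-type libraries and at least 50 donor reads in every library, and the 5 donors and 5 exons under the same conditions. It named the 10 largest rises and 10 largest falls of spliced reads among called groups with at least 5 CPM in the higher genotype and the same direction between every pair of libraries. The rule allowed 1 junction per gene; without gene names, 1 per donor, per acceptor or per skipping junction was taken. The table of gene names at hand is of GRCh38.p14 and has no exons, so coordinates were not matched to it; only gene lengths and gene order along chromosome 6 were compared, for MAP3K7 in the closing section. The 14 gene lists fixed beforehand, SF3B1 itself and the sequence around gained acceptors were not analysed here.

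The libraries of a genotype were not copies of each other: over intron groups with at least 50 reads, chi-square per degree of freedom was 9.59 in wild type and 7.55 in K700E. Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 ratios with a pseudocount of 0.5, looser and stricter read filters, thresholds of 5 and 20 points, multi-mapping reads added, a block for the replicate number, an overhang of at least 20 nt, dominant junctions included, DESeq2's size factors, unannotated introns included, and each library left out. The dispersion of 0 was chosen after the data were seen, and the estimated dispersion of the first run was then kept as an alternative. Also added then were all libraries thinned to the shallowest, and 1 exon version per skipping junction. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.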

Results

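Splice junctions were counted by RNA sequencing of polyadenylated RNA from K562 cells, an established human line derived from chronic myeloid leukaemia that keeps features of early erythroid cells. SF3B1 is a core protein of the U2 small nuclear ribonucleoprotein, the part of the spliceosome that recognises the branch point ahead of the acceptor (the downstream end of an intron). The comparison was between cells carrying the SF3B1 K700E substitution, a change found recurrently in myelodysplastic syndromes, and cells with a wild-type knock-in as the control. There were 2 libraries per genotype; nothing says that they came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. The wild-type libraries held 30565367 and 28909876 uniquely mapped junction reads, and the K700E libraries 28707695 and 14164888, so K700E replicate 2 had the lowest depth of the 4. In all, 608430 junctions were seen in at least 1 library, of which 261615 were marked as annotated in the files. Positions are those of the files, on hg19; junctions are given by the first and last base of the intron, and gene names were not attached to them.

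The first question was whether K700E changed which acceptor a donor was joined to. In K700E cells usage rose at 306 alternative acceptors and fell at 173, out of 21005 tested. Of the 306, 117 lay 10 to 30 nt upstream of the dominant acceptor and 114 over 100 nt upstream. Of the 306, 90 had a mean usage below 1% in wild-type cells, 47 had no wild-type read at all, and 35 took over 50% of the donor's reads in K700E. The median usage of the gained acceptors was 3.68% in wild type and 25.7% in K700E. Calls required an adjusted p below 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg) and a change of at least 10 percentage points. In 305 of the 306 gained and all 173 lost acceptors both K700E libraries lay beyond both wild-type libraries, an order that this selection from the same libraries favours. Other tools called fewer, 195 higher and 35 lower with DESeq2 and 157 and 15 with limma. With the dominant junctions included, 397 were higher and 396 lower, since a gain at one acceptor lowers the share of the donor's others. Far fewer acceptors were called without K700E replicate 1, while leaving out any other library changed the counts much less. With a library left out, here and below, the spread comes from the other genotype alone, so fewer calls can follow from the lost replicate. For acceptors, however, so large a drop came only with the loss of K700E replicate 1, which leaves the K700E library of lowest depth.

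The largest change among the acceptors named by the fixed rule was on chromosome 6, at an annotated intron from 91269954 to 91271340 on the minus strand. Its acceptor lies 20 nt upstream of the donor's dominant acceptor at 91269934. Its usage was 7.64% ± 2.31 (SD, n = 2) in wild type and 77.3% ± 9.996 in K700E (edgeR adjusted p = 2.68e-13), with between 64 and 194 reads leaving the donor per library. A second site on chromosome 6, the annotated intron from 10723475 to 10724788 on the plus strand, ended 14 nt upstream of the dominant acceptor and rose from 7.67% ± 2.07 to 71.6% ± 0.892 (n = 2 each; edgeR adjusted p = 7.71e-31). It had the deepest donor of the named acceptors, with 1140 to 2212 reads per library.

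Of the 20 named acceptors 18 rose and 2 fell. Of the 18, 10 lay 10 to 30 nt upstream of the dominant acceptor, with wild-type means from 0.774% to 10.8% and K700E means from 36.1% to 77.3%. Among these, the unannotated acceptor of the intron 45300424 to 45300861 on chromosome 17 (plus strand, 13 nt upstream) rose from 1.72% ± 0.809 to 51.3% ± 1.45. The intron 683396 to 685920 on chromosome 18 (minus strand, 15 nt upstream) rose from 3.66% ± 1.38 to 51.5% ± 2.59. The intron 120934020 to 120934204 on chromosome 12 (plus strand, 14 nt upstream) rose from 10.8% ± 1.23 to 58.0% ± 0.117. The intron 75356053 to 75356580 on chromosome 14 (plus strand, 19 nt upstream) rose from 0.915% ± 0.778 to 45.8% ± 1.18.

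The other 8 gained sites of the 18 lay downstream or farther away. On chromosome 9, the acceptor of the intron 125023778 to 125026993 (minus strand) lay 10 nt downstream of the dominant one and rose from 3.91% ± 0.515 to 46.3% ± 3.25. On chromosome 5, the acceptor at 869520, which ends an intron that starts at 870587 on the minus strand, lay 3823 nt upstream of the dominant acceptor and rose from 4.27% ± 0.633 to 68.4% ± 3.99. On chromosome 15, an unannotated intron of 106 nt from 23311201 to 23311306 (minus strand) rose from 0.886% ± 0.220 to 48.7% ± 1.31; with multi-mapping reads added the rise fell from 47.8 to 23.0 points. The larger of the named losses was on chromosome 16, where the intron 54954323 to 54957496 (minus strand) fell from 75.4% ± 9.70 to 9.96% ± 1.82; its acceptor lay 83 nt upstream of the donor's dominant acceptor. The edgeR adjusted p of the 20 ranged down from 3.13e-04, at the intron 140622982 to 140637843 on chromosome 9, which fell from 56.5% ± 7.19 to 22.6% ± 12.6 and was not called by limma (adjusted p = 0.128). That acceptor lay 21 nt downstream of its dominant one. Both named losses were the main acceptor in wild type, since dominance rests on mean usage over all 4 libraries. On chromosome 16 use therefore moved 83 nt downstream in K700E.

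**Figure D1:**
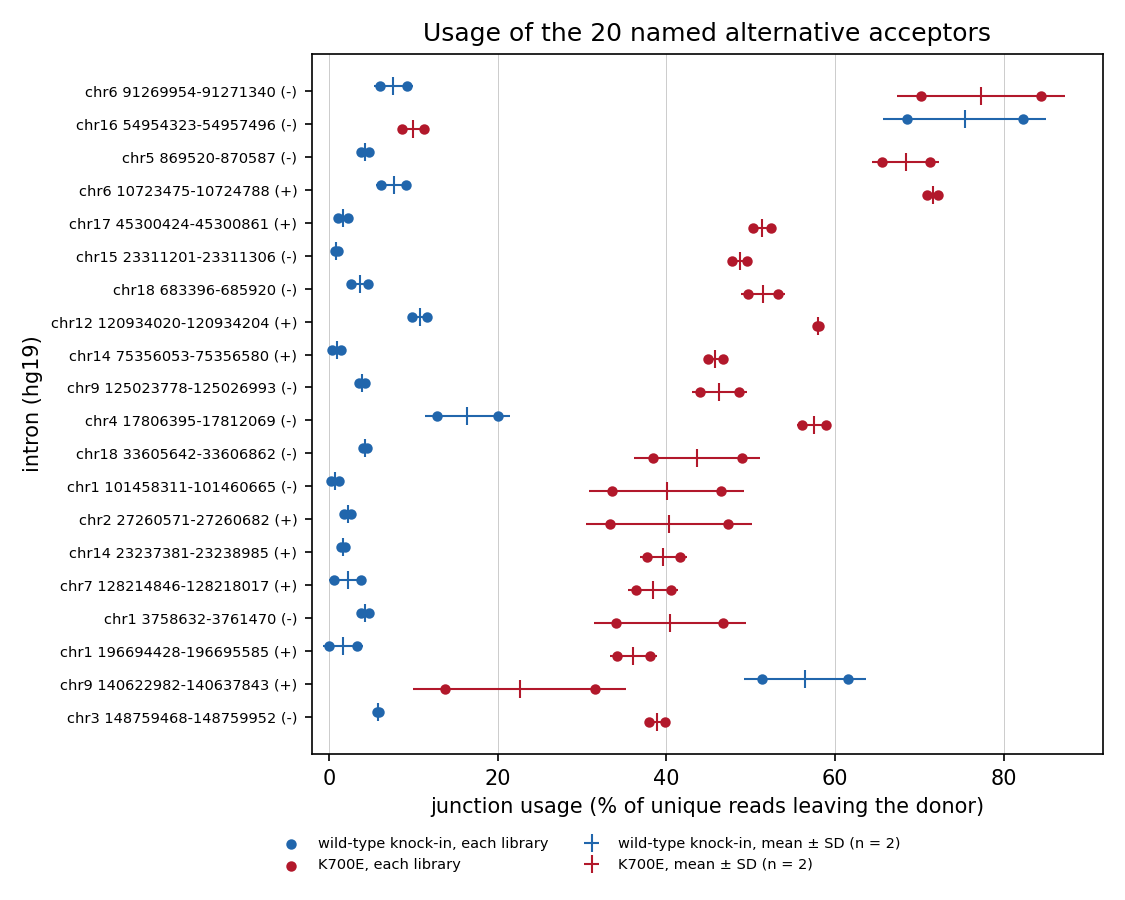
Usage of the 20 named alternative acceptors, as the percentage of the unique reads leaving the donor (horizontal axis) for each intron (vertical axis, hg19 positions and strand). Points are single libraries, vertical ticks with horizontal bars are mean ± SD (n = 2), blue is wild-type knock-in and red is K700E. The naming rule required both K700E libraries to lie on one side of both wild-type libraries, which was to the right in 18 of the 20.

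A short upstream position set the gained acceptors apart from the rest. Of the 306 gained acceptors, 117 (38.2%, exact 95% interval 32.8 to 43.9) lay 10 to 30 nt upstream of the dominant acceptor, against 779 of the 20699 other tested acceptors (3.76%). The odds ratio was 15.8 (Fisher's exact test, two-sided, p = 2.36e-80); junctions of one gene are not independent, so the p is approximate. In this window 13.1% of the 896 tested acceptors gained usage and 4 lost it, and the median gained acceptor went from 0.915% in wild type to 22.5% in K700E. Of the 431 unannotated acceptors in the window 72 gained usage and 0 lost it. In the mirror window, 10 to 30 nt downstream, 14 of 615 gained usage and 13 lost it. Of the 138 unannotated acceptors there 6 gained usage and 0 lost it. The gained acceptors of the upstream window had a median position of -18 nt.

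**Figure D2:**
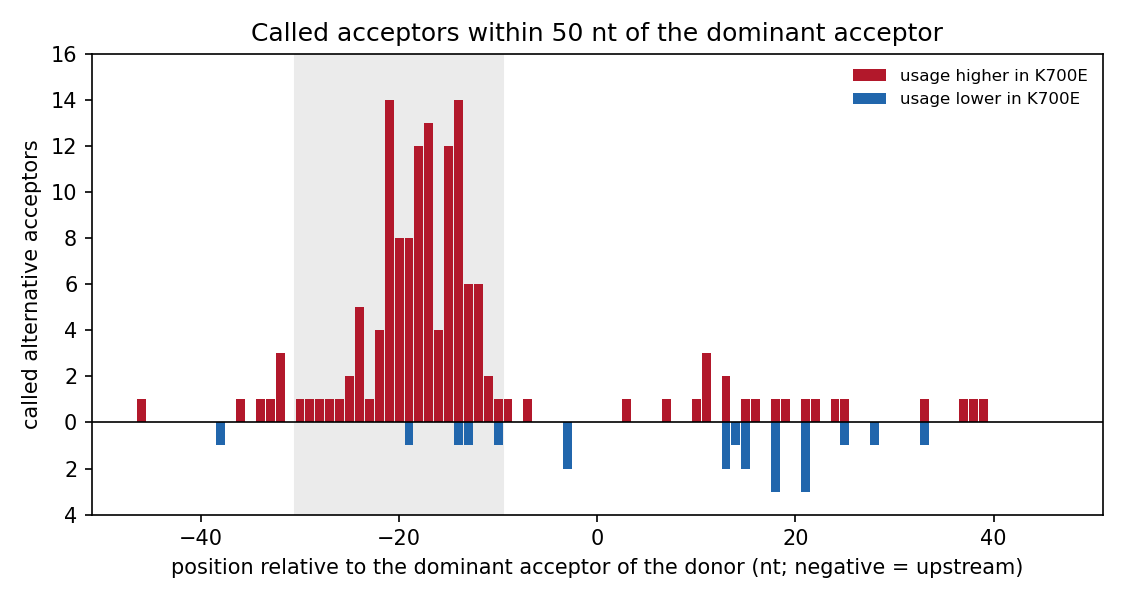
Number of called alternative acceptors (vertical axis, gains above the line and losses below it) by position relative to the dominant acceptor of the same donor in nt (horizontal axis, negative is upstream); red bars are acceptors with higher usage in K700E, blue bars lower. The shaded band from 10 to 30 nt upstream holds 117 gains and 4 losses.

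Donor choice, the other end of the intron, served as the class for comparison. Usage rose at 124 alternative donors and fell at 115, out of 19321 tested. Most of these calls lay over 100 nt from the dominant donor, with 86 gains and 26 losses downstream and 33 gains and 85 losses upstream. A donor that far away can belong to another exon, so changes of exon inclusion can enter these counts. Within 50 nt of the dominant site, 7 of 1984 tested donors were called (0.353%), against 167 of 4197 acceptors (3.98%; odds ratio 11.7, Fisher's exact test, two-sided, p = 2.27e-20). This comparison was not among the tests fixed beforehand. The 5 named donors all rose. The largest was the donor at 869359 on chromosome 5, joined to 865697 on the minus strand, which rose from 9.34% ± 0.750 to 49.8% ± 2.68 (n = 2; edgeR adjusted p = 3.82e-13), followed by the donor at 27260761 on chromosome 2, joined to 27261013 on the plus strand, which rose from 4.61% ± 0.231 to 43.9% ± 9.18. Closest to its dominant donor was that of the intron 34123530 to 34127523 on chromosome 21 (minus strand), 17 nt downstream, which rose from 22.8% ± 4.26 to 55.9% ± 3.33. The donor counts depended on the tool: DESeq2 called 17 higher and 2 lower, and limma called 0 in either direction, where 335 higher and 371 lower passed an unadjusted p below 0.05 with the 10-point change. Without wild-type replicate 1, wild-type replicate 2, K700E replicate 1 and K700E replicate 2 the counts were 61 and 72, 61 and 45, 18 and 13, and 70 and 32.

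Most of the called exon-skipping events moved towards inclusion in K700E. The read filter let in events near full skipping, which can hardly rise, so an even split need not be the neutral share. The skipping level fell in 441 events and rose in 165, out of 47947 tested, where an event is a skipping junction with 1 version of the exon between its ends. With 1 exon version per skipping junction, a choice made after the data were seen, 184 fell and 68 rose. Among events with at least 50 reads in every library, the largest change was at an exon of 160 nt on chromosome 5, from 869360 to 869519, whose flanking junctions are the acceptor and donor gained at this site above: its skipping level fell from 92.6% ± 0.690 to 35.9% ± 4.43 (n = 2; edgeR adjusted p = 4.89e-32). An exon of 131 nt on chromosome 15, from 23311070 to 23311200, was skipped at 79.2% ± 0.409 in wild type and 33.2% ± 1.04 in K700E, but 78.2% of the reads of its skipping junction were multi-mapping, so near-identical copies can share them. With multi-mapping reads added its change went from -46.0 to -24.1 points, and limma did not call it (adjusted p = 0.0639). An exon of 87 nt on chromosome 19, from 29101889 to 29101975, fell from 96.7% ± 0.492 to 56.3% ± 0.357, and one of 78 nt on chromosome 2, from 27260683 to 27260760, fell from 96.5% ± 0.449 to 56.3% ± 10.5. In the other direction, skipping of an exon of 119 nt on chromosome 4, from 17806730 to 17806848, rose from 14.4% ± 4.80 to 49.5% ± 2.97, which limma did not call (adjusted p = 0.168). Several named results describe the same exon. The chromosome 2 exon is flanked by the donor named above and by a named acceptor, and the chromosome 15 exon by the acceptor named above. The skipping junction of the chromosome 4 exon, from 17806395 to 17812069, is itself a named acceptor junction. The size of the set depended on the tool, 9 higher and 53 lower with DESeq2 and 4 and 29 with limma. It also fell to 102 and 282 without wild-type replicate 2, 16 and 60 without K700E replicate 1, and 70 and 186 without K700E replicate 2.

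Reads at junctions not marked as annotated took a slightly larger share in K700E. Their share of unique junction reads was 0.759% ± 0.054 (SD, n = 2) in wild type and 0.910% ± 0.034 in K700E. Per library it was 0.721% (Wilson 95% interval 0.718 to 0.724) and 0.798% (0.794 to 0.801) in wild type, and 0.886% (0.883 to 0.889) and 0.935% (0.930 to 0.940) in K700E. These intervals cover counting error only. Both K700E libraries lay above both wild-type libraries, but the exact permutation test, two-sided, gave p = 0.333, the smallest that 2 against 2 can give. The difference was 0.151 points, and 0.0871 points when only junctions with at least 10 unique reads were used.

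Spliced reads, summed over annotated introns joined by a shared end, served as a measure of expression by locus. They were higher in K700E at 3764 of 94259 intron groups and lower at 1805 (edgeR's quasi-likelihood test, adjusted p below 0.05). At least a 2-fold rise was found in 2354 groups and at least a 2-fold fall in 657. Most groups (66.9%) were a single intron, so one gene can count several times. The balance differed by chromosome, from 9.59% higher and 0.869% lower on chromosome 8 to 1.46% higher and 3.53% lower on chromosome 22. Among called groups with at least 5 CPM in the higher genotype and one direction in every pair of libraries, the largest rise was on chromosome 8, over 15 introns from 93904295 to 93978234 (minus strand), from 0.229 ± 0.195 to 10.3 ± 4.20 CPM (counts of spliced reads scaled to the same library total) (log2 fold change 5.44, SE 0.53, n = 2, adjusted p = 0.00857). Wild type held 15 reads there, and the log2 fold change was 4.76 without wild-type replicate 1 and 6.70 without wild-type replicate 2. On chromosome 4, 4 of the 10 named risers lay between 79475643 and 79518472 on the plus strand. The group of 8 introns there rose from 1.497 ± 0.132 to 15.3 ± 1.34 CPM (log2 fold change 3.35, SE 0.21). The intron from 46989535 to 46990918 on chromosome 16 (minus strand) rose from 0.260 ± 0.021 to 8.28 ± 1.99 CPM, and the 3 introns between 65269865 and 65271796 on chromosome 11 (plus strand) from 0.718 ± 0.409 to 8.39 ± 0.799.

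The named falls were smaller than the named rises. The intron from 38976427 to 38976513 on chromosome 17 (minus strand) fell from 5.99 ± 1.20 to 1.33 ± 0.849 CPM (log2 fold change -2.30, SE 0.40, edgeR adjusted p = 0.0225, n = 2). Introns from 38975987 to 38976300 next to it fell from 5.96 ± 1.503 to 1.37 ± 0.791. Both lost their call without wild-type replicate 1 (log2 fold change -2.07 and -1.94, edgeR adjusted p = 0.0835 and 0.0704) and without K700E replicate 1 (-1.64 and -1.63, adjusted p = 0.0631 and 0.0775). Those from 212515623 to 212519144 on chromosome 1 (plus strand) fell from 8.08 ± 1.03 to 1.89 ± 0.485. Without wild-type replicate 1 the counts were 1315 higher and 321 lower, and without wild-type replicate 2 they were 2090 and 1147. Without K700E replicate 1 they were 825 and 44, without K700E replicate 2 they were 2788 and 1099, and with unannotated introns included 2210 and 946.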

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

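The dispersion of 0 behind the main counts of acceptors, donors and skipping, the thinned libraries and 1 exon version per skipping junction were chosen after seeing the data. The estimated dispersion was that of the first run. In each setting that follows, the first number is the count higher in K700E and the second the count lower. For acceptors (306 and 173), DESeq2 gave 195 and 35, limma 157 and 15, nearly no filter 184 and 57, at least 100 reads per donor 72 and 68, and thresholds of 5 and 20 points 488 and 138 higher, the latter with 52 lower. The lower count was 90 with an estimated dispersion and 107 after thinning. With dominant junctions included the counts were 397 and 396, so the excess of gains holds only for the alternative acceptors. Leaving out 1 library gave 159 to 348 higher and 53 to 228 lower. For donors (124 and 115), DESeq2 gave 17 and 2, limma 0 and 0, nearly no filter 36 and 29, at least 100 reads 45 and 50, an estimated dispersion 43 and 30, thinning 55 and 49, and 20 points 40 and 37, with 58 lower when multi-mapping reads were added. Leaving out 1 library gave 18 to 70 higher and 13 to 72 lower. For skipping (165 and 441), DESeq2 gave 9 and 53, limma 4 and 29, nearly no filter 87 and 284, at least 100 reads 89 and 214, an estimated dispersion 50 and 157, thinning 59 and 219, 1 exon version 68 and 184, 20 points 51 and 197, and 5 points 257 higher. Leaving out 1 library gave 16 to 156 higher and 60 to 412 lower. For spliced reads (3764 and 1805), unannotated introns gave 2210 and 946, and leaving out 1 library 825 to 2788 higher and 44 to 1147 lower; the other settings stayed within 1.5 times. Fewer junctions pass the stricter filter and fewer libraries enter the left-out fits; the cause of the other moves was not tested. The share of gained acceptors lying in the upstream window kept its direction and its side of the threshold in each of the 8 alternatives, at 33.3% to 56.7%, and at 36.2% to 44.7% with 1 library left out. The unannotated share differed by 0.151 points between genotypes, by 0.087 with junctions of at least 10 reads, and by 0.113 to 0.189 with 1 library left out. Of the 20 named acceptors 19 were called in each alternative in which they were tested. The same held for 0 of 5 donors, 3 of 5 exons and 8 of 20 intron groups, and none turned direction. The groups starting at 28549477 on chromosome 16 and at 79516592 and 79507505 on chromosome 4 are not among the 8 only because DESeq2 gave them no adjusted p. The replicate numbers do not pair the libraries by any label; same-numbered libraries deviated together with r = 0.125 over intron groups and 0.083 over acceptor usage. With the replicate block the counts were 337 and 209 acceptors, 121 and 113 donors, 136 and 391 skipping events, and 4627 and 2302 intron groups. Tests of gene lists and of sequence at acceptors were not run.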

Other observations

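The tests of exon versions, thinning, window and block shuffles, intron density, MAP3K7 and its neighbours, splits of the libraries, and the counts by position in this part were chosen after the results were seen. Acceptors short of the threshold leaned the same way as the called ones. Of the 775 uncalled acceptors 10 to 30 nt upstream of the dominant one, 72.9% (exact 95% interval 69.6 to 76.0) had a higher mean usage in K700E, with a median change of 0.956 points. Of the 588 uncalled acceptors 10 to 30 nt downstream, 300 did (exact interval 46.9% to 55.1%; Fisher's exact test, two-sided, odds ratio 2.58, p = 1.24e-16). Among calls within 50 nt, 140 of 167 moved use towards the upstream site (83.8%, exact interval 77.4 to 89.1; sign test p = 1.35e-19). The introns ending at gained acceptors of the upstream window had a median length of 1387 nt, against 703 nt for the other acceptors of the window. Reads at introns of the AT-AC class, which the minor spliceosome removes in part, took 0.0983% ± 0.0016 of unique reads in wild type and 0.0881% ± 0.00048 in K700E (n = 2; exact permutation test, two-sided, p = 0.333, the smallest possible).

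Far from the dominant site, shorter introns gained. Over 100 nt away, gained acceptors lay upstream in 114 cases and downstream in 39, and lost ones in 40 and 106 (Fisher's exact test, odds ratio 7.75, p = 1.73e-16). Gained donors lay downstream in 86 cases and upstream in 33, and lost ones in 26 and 85 (Fisher's exact test, odds ratio 8.52, p = 6.36e-14). Donors and acceptors of one exon enter both counts: 56 of the 239 called donors lay within 1000 nt of a called acceptor, against 26 of 2000 uncalled donors drawn at random.

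Skipping fell more often than it rose, in 441 of 606 called events (72.8%, exact interval 69.0 to 76.3). Counting several versions of an exon was not the whole cause, since with 1 version per skipping junction the lowered share was 73.0% (67.1 to 78.4). Exons opened only by unannotated acceptors were not the whole cause either: with all 3 junctions annotated it was 70.5% (64.9 to 75.8). After thinning to equal totals of unique junction reads it was 78.8% (73.5 to 83.4), so unequal totals were not the whole cause. RNA quality and fragment length could not be measured here and stay open as causes of the lean towards inclusion, as does the K700E genotype. The read filter also stays open: it asked for at least 10 reads of the skipping junction but fewer of each inclusion junction. Events near full skipping, which can hardly rise, were therefore tested, so an even split need not be the neutral share. This effect was not tested.

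Nearby introns moved together between genotypes: the SD of the median log2 change over 281 windows of 10 Mb was 0.241, above the highest of 1000 shuffles of single intron groups (0.0669) and above the larger SD between libraries of a genotype, 0.105 on the same scale. Moving blocks of 1 Mb whole, which keeps introns of one gene mostly together, gave a median SD of 0.200 and at most 0.233, so genes and close neighbours could account for most of it but not all. Adjacent windows correlated (r = 0.338, permutation p = 1e-04, the smallest possible), though also within wild type (0.372) and within K700E (0.472), so this is not specific to the genotype. GC bias between libraries cannot be told apart from the genotype here, because no genome was used: intron density and length, which stand in for GC content, explained 34.3% of the variance and left an SD of 0.195 (bootstrap interval 0.175 to 0.214) against a limit of 0.210 set for excluding it. The same fit explained 0.502% of the variance between the wild-type libraries and 0.278% between the K700E libraries. A bias shared by both libraries of a genotype would not show in those values and stays open. By chromosome, the median log2 change ranged from -0.212 on chromosome 22 to 0.318 on chromosome 8. In the chromosome 22 windows from 10 to 20 and from 20 to 30 Mb, the values between genotypes were -0.410 and -0.444. Those between the K700E libraries were of similar size, 0.514 and 0.610, so the fall there is not clear of the spread between libraries. In the chromosome 8 window from 80 to 90 Mb the values were 1.01 between genotypes and -0.450 between the K700E libraries. A difference in chromosome copies between clones of K562 was not tested and may contribute.

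The largest change among the named acceptors may lie in MAP3K7, a kinase of stress signalling that the series title names; its place was recognised from general knowledge before these tests were written. The annotated introns linked to it span 72945 nt, 99.3% of the MAP3K7 length in the GRCh38.p14 table, on the same chromosome, where 46 of 1049 protein-coding genes have a compatible length and 2, MAP3K7 included, are at least this close. With MAP3K7 in that place, 15 of 20 neighbouring intron groups matched gene lengths in the table's order; the best other gene reached 11. No coordinates were converted, so the assignment is a hypothesis.

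Donors with a gained acceptor within 50 nt of the dominant one were compared by reading frame. Loss of transcripts with a shifted reading frame would lower the reads of those whose gained acceptor lies a number of nt away that is no multiple of 3. The median log2 change of donor reads was -0.06 at 85 such donors and -0.0037 at 60 others, a difference of -0.061 (bootstrap interval -0.34 to 0.19; permutation p = 0.723), so such a loss was not detectable here and is not excluded, although the bound written beforehand would have read a p above 0.05 as excluding it. With 3 possible splits of the 4 libraries into equal groups, a share under 0.05 is out of reach. The real split, 1 of the 3, called 479 acceptors, 239 donors, 606 skipping events and 5569 intron groups, and the highest of the others called 0, 2, 11 and 0. Each other split puts 1 library of each genotype in each group, so any difference between genotypes adds to its spread and lowers its calls. Those counts are therefore not a level of false calls.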
